A study of Mus musculus with 20 samples.

How the data were processed

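Small RNA libraries from the right ventral hippocampus of male C57BL/6JOlaHsd mice were compared between 10 animals given cannabidiol (CBD) and 10 given vehicle. Per the labels' protocols, total RNA was extracted with Trizol and small RNA libraries were made with an Illumina TruSeq kit and size-selected on a Pippin Prep. The kit and protocol name no molecular identifiers, so reads are not independent molecules and counting error is only part of the spread between libraries.

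Per the submitters' processing notes, the build was mm10 and edgeR and limma were used by the authors, with no version or role. The aligner, the read counter and the miRNA catalogue are not given in the sources used here. The authors deposited log2 expression values for 281 miRNAs in 20 columns, each named by a mouse number that matched 1 sample title. The rule by which the authors limited the table to 281 miRNAs is not given in the sources used here. Every deposited log2 value had the form log2((n + 0.5) / (L + 1) × 1000000), with a whole read number n and 1 effective library size L per column. This held for 100% of the values in each of the 20 libraries within a tolerance of 1e-06 reads, so whole reads were recovered. The effective library divided by the total reads of the deposited technical table gave a scaling factor between 0.693 and 1.17, with a geometric mean of 0.995 over the 20 libraries. The header names these totals a library size. Whether they count all sequenced reads or only those assigned to miRNAs is not given in the sources used here. The technical table also lists, per the file headers, a number of miRNAs and a run number from 1 to 4 for each library. The meaning of the run number is not given in the sources used here. The run held 5, 6, 4 and 5 libraries for runs 1 to 4, of which 3, 3, 2 and 2 were from CBD mice. Runs followed the mouse numbers, 1 to 7, 14 to 21, 22 to 27 and 39 to 43. Within a run, mice of the same treatment mostly had consecutive numbers. A difference shared by mice of neighbouring numbers can therefore not be fully told apart from treatment, and the main test takes the 20 mice as independent.

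The authors' deposited comparison table gives, per the file headers, a log2 fold change, a mean log2 level, p-values, adjusted p-values, and a t and a log-odds score for each of 281 miRNAs. It also gives a fold column, which the authors computed as a ratio. In 281 of 281 rows this ratio was 10 to the power of the log2 fold change, within 1e-06, so it overstates the size of each change and was not used. The authors' mean levels differed from the means of the 20 columns by up to 0.459 on the log2 scale, with an SD of 0.114 over miRNAs, so that table was not made from these 20 columns alone as they stand. A shorter deposited table repeats 66 rows, which were those with an unadjusted p under 0.05. In it the row of miR-24-3p repeats the values of miR-24-2-5p, and the values of the whole table were used for both.

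The main test was limma 3.58.1 in R 4.3.3, fitted to the deposited log2 values as they stand, with treatment as the only term and a trend of the variance with the mean level. Differences are CBD minus vehicle, tests are two-sided, and p-values were adjusted by Benjamini and Hochberg over 281 miRNAs with a threshold of 0.05. The low-value filter, a log2 value above 0 in at least 10 samples, removed no miRNA, and neither did the stricter filter, a mean above 10 CPM (reads per 1000000). The values being on the log2 scale, the alternatives with other pseudocounts for linear values were not applicable. Because the technical table holds a run number, a fit with run as a further term was added after seeing the data, and for the miRNAs named by rule its value is printed beside the main one, with the difference within each run or with the signs within runs. An exact permutation test of the treatment labels within runs used all 12000 relabellings.

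Before the data were examined, 22 lists of miRNAs were fixed by name, and 15 had at least 3 measured members. They were tested with camera at a preset correlation of 0.01 between miRNAs, with camera at an estimated correlation, and with fry. The share of squared distance between libraries that lay between the groups was tested with 100000 permutations of the labels, as were the differences in library yield. The miRNAs named in the text follow a rule fixed at the same time. Of the miRNAs past the threshold, the 10 largest increases and the 10 largest decreases were to be named, filled up to 20 with the smallest unadjusted p where fewer passed. To these were added the 10 of the authors' short list with the smallest p, the 4 members with the smallest p of any called list, and 14 miRNAs fixed by name, of which 11 were measured. The rule gave 32 miRNAs. Any other miRNA named was chosen after its values were seen.

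The alternatives tried were other filters, values rescaled to 1 total, median centring, quantile normalisation, median-of-ratios size factors, other variance models, array weights, voom weights on the recovered reads, 5 reads added before log2, library reads, mouse number or run as terms, random blocks, an exact Wilcoxon test, a threshold of 0.1, and leaving out each library. The closing section gives their effect.

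Hairpin positions were taken from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, by matching miRNA names to hairpin gene symbols. At least 1 hairpin was matched for 279 of 281 miRNAs, 8 of them through RefSeq synonyms, and 27 have more than 1 hairpin, for which the source of the reads cannot be told from the mature name. The GC content of the hairpin side that holds the mature arm served in a check of GC bias, as the slope of each library's log2 deviations on GC, with 279 miRNAs.

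The tests were tested on simulated data drawn for the same 281 miRNAs, library sizes and spread of CBD minus vehicle, with 60 miRNAs changed in each of 20 repeats. Without a run term, 35.2% of changes of 1.5-fold, 77.2% of changes of 2-fold and 94.2% of changes of 3-fold were called, and 3.68% of the calls were false. With the run term these shares were 46.2%, 88.5% and 98.0%, and 3.08% of the calls were false. The draws were independent between miRNAs and held no effect of run, unlike the real libraries. The shares called and the shares of false calls may therefore be too favourable for these data. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.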

Results

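Cannabidiol (CBD), a plant cannabinoid that does not produce the intoxication of tetrahydrocannabinol, was given by intraperitoneal injection at 200 mg/kg/day for 5 days to naïve male mice. The mature miRNAs of the right ventral hippocampus, a part of the hippocampus linked to emotional behaviour, were then sequenced in 10 treated and 10 vehicle mice. The comparison asks how CBD affects miRNA levels in animals without a disease model. Total reads per library, taken from the listed library size, lay between 242178 and 1245429. The mean was 693734 ± 269489 reads (SD, n = 10) with CBD and 700496 ± 342574 (SD, n = 10) with vehicle, a difference of -6763 reads (permutation test, p = 0.961, adjusted p = 0.961 over 5 library measures). Within runs 1 to 4 the difference was 196760, 52411, 38997 and -270406 reads. The number of miRNAs listed per library was 749.8 ± 69.6 with CBD and 743.1 ± 67.4 with vehicle (SD, n = 10 each, permutation test, p = 0.830, adjusted p = 0.961). Within runs 1 to 4 it differed by 45.3, 11.7, -20.5 and -20.3 miRNAs.

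In 19 of the 20 libraries the largest share of reads was taken by miR-434-3p, a miRNA of the imprinted Dlk1-Meg3 region, and in CBD replicate 3 by the neural miR-9-5p. That top miRNA took 22.9% ± 5.87 of the reads with CBD and 20.6% ± 7.0 with vehicle (SD, n = 10 each, permutation test, p = 0.441, adjusted p = 0.762). The 281 miRNAs of the table held 99.4% ± 0.0743 of the listed library size with CBD and 99.3% ± 0.0719 with vehicle (SD, n = 10 each). This difference had p = 0.0407 in a permutation test and adjusted p = 0.203, and its sign turned in run 4. These are not shares of all sequenced reads if the library size counts miRNA reads only. The lowest read number of any miRNA in any library was 2. Replicate pairs within a group correlated at 0.868 to 0.991 across miRNAs. Each of the 90 pairs differed by more than the counting error of reads alone, with a chi-square per degree of freedom of at least 19.2. That measure leaves out the spread between mice and other library noise.

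Whole profiles differed more between runs than between treatments. The 4 runs held 41.8% of the squared distance between libraries, against 15.8% expected between 4 random sets (permutation test, p = 1.0e-05, the smallest that 100000 resamples can give). Treatment held 6.83%, against 5.26% expected between 2 random groups (permutation test, p = 0.209). After the run means were removed, treatment held 11.6% of what was left, with p = 0.0278 in an exact permutation test within runs. In the limma fit with treatment and run, 135 of 281 miRNAs differed between runs at an adjusted p under 0.05. The largest difference by p was that of miR-34b-5p, a miRNA of ciliated cells, with mean log2 levels of 6.93, 6.79, 10.29 and 8.53 in runs 1 to 4, a miRNA chosen after its values were seen.

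**Figure D1:**
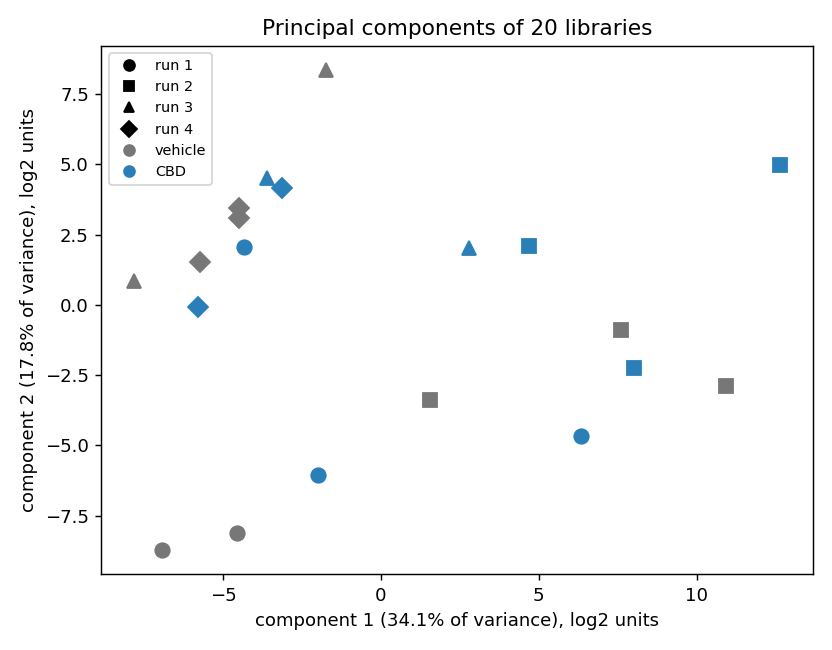
Scores of the 20 libraries on the first 2 principal components of the log2 values, in log2 units, with 34.1% and 17.8% of the variance; colour gives the treatment and the symbol the run. The 6 libraries of run 2 lie to the right of 0 on component 1, and CBD and vehicle libraries overlap.

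In the comparison of CBD with vehicle no miRNA passed the adjusted threshold, and the largest differences were of about 2-fold. The largest increase was that of miR-320-5p, with a log2 level of 8.76 ± 0.86 with CBD and 7.59 ± 0.93 with vehicle (SD, n = 10 each), and the largest decrease that of miR-153-3p, a neuronal miRNA, with 6.72 ± 1.33 and 7.78 ± 0.65. Of the 281 miRNAs, 0 had an adjusted p under 0.05 in the limma test, the lowest adjusted p was 0.470, and 22 had an unadjusted p under 0.05, of which 7 were higher and 15 lower with CBD. About 14.1 would be expected by chance. Centring on the median miRNA gave 13 higher and 4 lower at an unadjusted p under 0.05, so the balance of directions depends on the scaling. The count at an adjusted p under 0.05 was also 0 with an exact Wilcoxon test, with voom weights and with the run term, and 24 with array weights, which gave the 5 libraries of run 4 weights of 1.46 to 4.62. With array weights and the run term it was 0. The run term raised the count at an unadjusted p under 0.05 to 42, with 12 higher and 30 lower and a lowest adjusted p of 0.185.

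Among the miRNAs with the smallest p, those higher with CBD did not all vary independently between libraries. The levels of miR-320-5p and of miR-6236, a member of the rRNA- or tRNA-like list below, were both lowest in vehicle replicate 6, at 6.08 and 8.87. Both were highest in CBD replicate 6, at 10.18 and 12.43, so their differences may not be separate results. For miR-320-5p the log2 difference was 1.17 (SE 0.37, unadjusted p = 0.00435, limma adjusted p = 0.470), with 9 of 10 CBD libraries above the vehicle mean. With the run term it was 1.15, and within runs 1 to 4 it was 0.95, 1.31, 0.57 and 1.65. Its hairpin lies on chromosome 14 at 70443510 to 70443591 (GRCm38), where no other gene is annotated on either strand. For miR-409-5p, in the Dlk1-Meg3 region on chromosome 12 at 109743158 to 109743236 within an intron of the noncoding gene Mirg, it was 1.05 (SE 0.33, unadjusted p = 0.00463), again with 9 of 10 CBD libraries above the vehicle mean. It was 1.02 with the run term, and 0.11, 0.63, 1.53 and 1.98 within runs 1 to 4. For miR-30c-2-3p, from chromosome 1 at 23291701 to 23291784, it was 0.64 (SE 0.22, unadjusted p = 0.00682), with all 10 of 10 CBD libraries above the vehicle mean. Its value was 0.63 with the run term, and 0.54, 0.70, 0.45 and 0.80 within runs. The abundant miR-541-5p, also in an intron of Mirg, had a difference of 0.37 (SE 0.16, unadjusted p = 0.0301) at 12966 mean reads with CBD, 0.40 with the run term and 0.39, 0.48, 0.74 and 0.04 within runs. For miR-3535, which was not matched to a hairpin, it was 0.84 (SE 0.32, unadjusted p = 0.0150), 0.79 with the run term and 0.57, 0.84, 0.21 and 1.42 within runs.

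**Figure D2:**
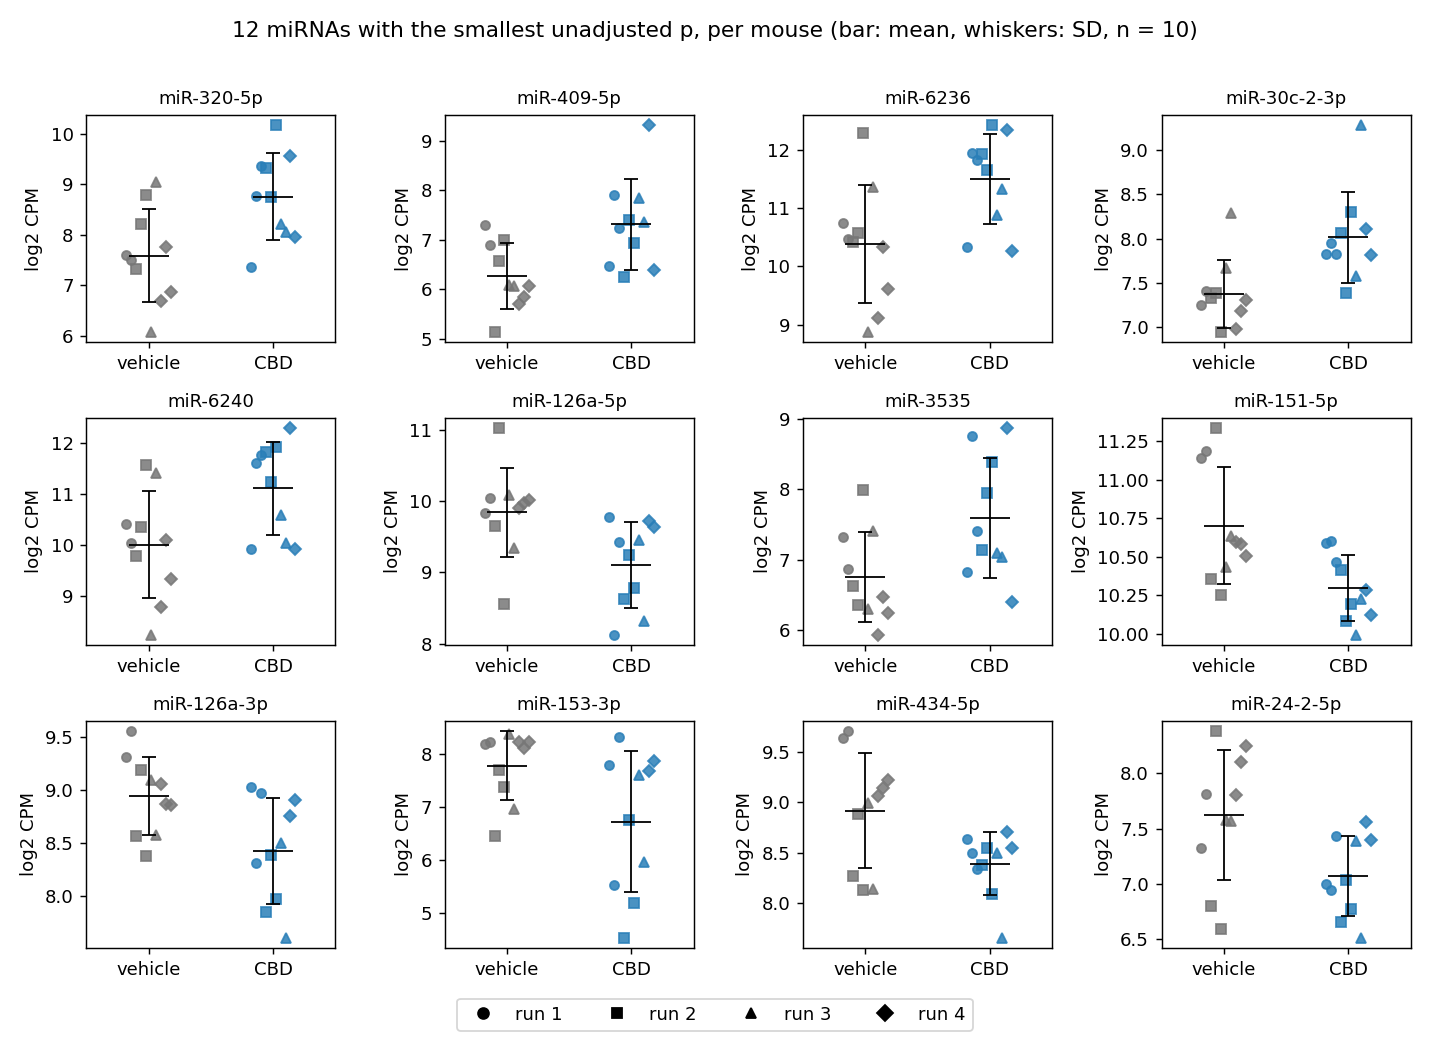
Log2 CPM (reads per 1000000) of the 12 miRNAs with the smallest unadjusted p, 1 point per mouse, with the mean as a bar and the SD as whiskers (n = 10 per group); the symbol gives the run. The groups overlap in each panel, and all 10 CBD mice lie above the vehicle mean for miR-30c-2-3p and below it for miR-151-5p.

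The miRNAs lower with CBD included both arms of miR-126a, which lies in the endothelial gene Egfl7 on chromosome 2 at 26591357 to 26591429 and marks blood vessels. The log2 difference was -0.74 (SE 0.27, unadjusted p = 0.0108) for miR-126a-5p and -0.52 (SE 0.21, unadjusted p = 0.0202) for miR-126a-3p, with 10 and 8 of 10 CBD libraries below the vehicle mean. They had -0.71 and -0.54 with the run term. Within runs 1 to 4 the values were -0.83, -0.86, -0.83 and -0.29 for the first and -0.66, -0.64, -0.78 and -0.10 for the second. For miR-151-5p, in an intron of Ptk2 on chromosome 15 at 73254815 to 73254882, it was -0.40 (SE 0.16, unadjusted p = 0.0200), with 10 of 10 CBD libraries below the vehicle mean. It was -0.45 with the run term, and -0.61, -0.41, -0.43 and -0.36 within runs 1 to 4. This miRNA had the smallest p in the exact permutation test within runs, 0.000333, with an adjusted p of 0.0937. For miR-153-3p, in an intron of Ptprn2, it was -1.06 (SE 0.43, unadjusted p = 0.0204) at a lowest level of 8 reads in 1 library, -1.04 with the run term and with the same sign in 4 of 4 runs. The oligodendrocyte miRNA miR-338-3p, in an intron of Aatk, had -0.62 (SE 0.26, unadjusted p = 0.0251), -0.64 with the run term and -0.91, -0.53, -1.22 and -0.02 within runs. Other miRNAs of the smallest p were miR-24-2-5p at -0.55, miR-148a-3p at -0.50 and miR-195a-5p at -0.40, with -0.51, -0.44 and -0.38 with the run term and the same sign in 4 of 4 runs. None of these passed after adjustment, with adjusted p between 0.470 and 0.549.

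The blood vessel and oligodendrocyte lists had negative means, with calls that depend on the setting. All 4 measured members of the blood vessel list had a negative difference, with a mean of -0.45, and 2 of them passed when adjusted over the list alone, against 0 over all miRNAs. These were miR-126a-5p and miR-126a-3p, the 2 arms of 1 hairpin and so not independent. Of the others, both of smooth muscle, miR-145a-5p had -0.55 and miR-143-3p -0.02. The camera test gave an adjusted p of 0.0503, or adjusted p = 0.284 with an estimated correlation, and fry, which tests a list against no change, 0.0972. With the run term the adjusted p by camera was 0.0669, or adjusted p = 0.360 with an estimated correlation, and 3 of the 4 members passed over the list alone, while miR-143-3p turned to 0.03. The mean of the list was then -0.46 (95% interval -0.80 to -0.12, not adjusted over lists). The mean of the blood vessel list within runs 1 to 4 was -0.52, -0.49, -0.58 and -0.26. The oligodendrocyte list had 5 measured members. Both arms of miR-338 were among them, as were miR-219a-5p and miR-219a-2-3p, so the members are not independent. The remaining member, miR-23a-3p at -0.51, lies next to miR-24-2-5p, which was also lower but is not in the list. All 5 members were lower, with a mean of -0.51, from miR-338-3p at -0.62 and miR-219a-5p at -0.61 to miR-219a-2-3p at -0.30. When adjusted over the list alone, 0 passed, or 1 with the run term. Its camera adjusted p was 0.0503, or adjusted p = 0.333 with an estimated correlation, and 0.0460 with the run term, where the estimated correlation gave an adjusted p of 0.360 and the mean was -0.56 (95% interval -0.94 to -0.17, not adjusted over lists). Within runs 1 to 4 the mean of the oligodendrocyte list differed by -0.75, -0.51, -1.19 and 0.11, so its sign turned in run 4. With array weights the mean was -0.17 (camera adjusted p = 0.808), and miR-219a-2-3p turned to 0.082. The difference of miR-219a-2-3p with the run term was -0.35, and within runs it was -0.04, -0.54, -0.85 and -0.01. When each library was left out in turn without the run term, the camera adjusted p was 0.0228 to 0.220 and under 0.05 in 8 of 20 fits for the oligodendrocyte list, and 0.0253 to 0.0962 and under 0.05 in 11 of 20 for the blood vessel list. The 0.220 was without vehicle replicate 7, the library with the highest miR-219a-2-3p.

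The called list was that of entries resembling fragments of rRNA or tRNA, which stood higher with CBD relative to the other miRNAs (camera adjusted p = 0.0293, 4 of 6 members higher and 2 lower, mean log2 difference 0.42). The call was lost with an estimated correlation, at an adjusted p = 0.284. Against no change, rather than against the other miRNAs, fry gave an adjusted p of 0.273. When adjusted over the list alone, 2 members passed, against 0 over all miRNAs. These were miR-6236, with a difference of 1.11 (SE 0.37, unadjusted p = 0.00585), and miR-6240, with 1.11 (SE 0.40, unadjusted p = 0.0105), both with 8 of 10 CBD libraries above the vehicle mean. Both had 1.06 with the run term. Within runs 1 to 4 the values were 0.77, 0.91, 0.99 and 1.61 for the first and 0.87, 1.09, 0.49 and 1.69 for the second. The levels of miR-6236 and miR-6240 went together between libraries, with 8.87 and 8.24 in vehicle replicate 6 and 12.34 and 12.28 in CBD replicate 9. They are therefore not independent. The next members were miR-5099 at 0.40 (SE 0.20) and miR-1983 at -0.10 (SE 0.23), with 0.37 and -0.17 with the run term and the same sign in 4 and 2 of 4 runs. Of the 4 higher members, miR-3963 stood at only 0.0019. The median of the list was 0.20, and within runs 1 to 4 its mean was 0.20, 0.55, 0.16 and 0.61. With the run term the adjusted p by camera was 0.0460, adjusted p = 0.360 with an estimated correlation and 0.322 with fry, and the mean difference of 0.40 had a 95% interval of -0.03 to 0.83. With the GC slope of each library added to the run term the camera adjusted p was 0.0523. Without the run term it was 0.0531, 0.0615 and 0.0509 without CBD replicate 4, vehicle replicate 6 and CBD replicate 9.

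**Figure D3:**
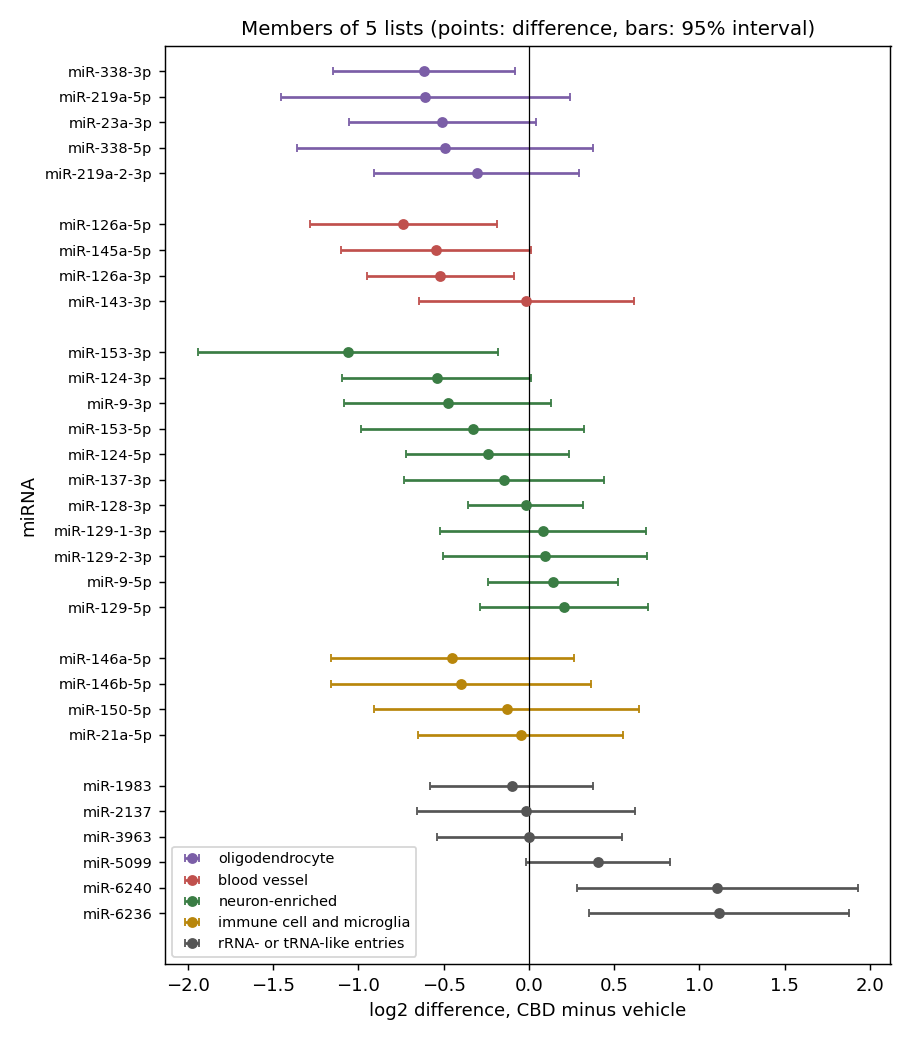
Log2 differences, CBD minus vehicle, of the measured members of 5 lists fixed by name, as points with 95% intervals from the limma fit (n = 10 per group). All 5 oligodendrocyte and all 4 blood vessel members lie below 0, and miR-6236 and miR-6240 lie above 1.

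Neuronal and synaptic miRNAs showed no common direction that passed a test. In the neuron-enriched list 7 of 11 members were lower and 4 higher, with a mean of -0.21 (camera adjusted p = 0.642). Its members miR-124-3p, miR-9-5p and miR-128-3p had differences of -0.54 (SE 0.27), 0.14 (SE 0.19) and -0.02 (SE 0.16). With the run term miR-124-3p had -0.57 at an unadjusted p of 0.0140 and an adjusted p of 0.225, and its sign turned in run 4, while miR-9-5p and miR-128-3p had 0.18 and 0.0027, with the same sign as without it in 3 and 2 of 4 runs. In the synapse and dendritic spine list 6 of 12 members were higher and the mean was -0.03, while the median, 0.01, and the camera test pointed up (adjusted p = 0.642). Its activity-regulated members miR-132-3p and miR-212-3p had 0.37 (SE 0.25) and 0.17 (SE 0.17), or 0.41 and 0.19 with the run term. Within runs miR-132-3p went from 1.05 in run 1 to -0.44 in run 4, and miR-212-3p had the same sign in 3 of 4 runs. The p53-linked miR-34a-5p had -0.40 (SE 0.23), or -0.45 with the run term, and its sign turned in run 4. Of the 55 members of the imprinted Dlk1-Meg3 list, 20 were higher and 35 lower, with a mean of -0.09 (camera adjusted p = 0.719), and 8 had an unadjusted p under 0.05. They went both ways, with miR-409-5p and miR-541-5p higher and miR-434-5p at -0.53, miR-666-5p at -0.62, miR-300-3p at -0.60, miR-376b-5p at -0.56 and miR-370-3p at -0.37. These last 5 had -0.54, -0.58, -0.65, -0.48 and -0.36 with the run term, and the sign turned for miR-370-3p in run 3.

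The other lists did not pass. The miR-181 family had a mean of 0.19 with 5 of 7 members higher (camera adjusted p = 0.0523, adjusted p = 0.284 with an estimated correlation). The immune cell and microglia list had 4 of 4 members lower and a mean of -0.26 (adjusted p = 0.642), with miR-146a-5p at -0.45 (SE 0.34) and miR-21a-5p at -0.05 (SE 0.29). These had -0.42 and -0.03 with the run term, with the same sign in 3 and 1 of 4 runs. The choroid plexus and ependyma list had a mean of 0.10 (adjusted p = 0.642), with miR-204-5p at 0.45 (SE 0.38), or 0.44 with the run term and the same sign in 2 of 4 runs. The means were -0.11 for the let-7 family, -0.15 for the miR-29 family, -0.15 for the endocrine list, -0.11 for the miR-34 family and 0.11 for the miR-17-92 cluster, with adjusted p between 0.642 and 0.754. The miR-30 family had a mean of -0.01 and a median of -0.13, while its test pointed up (adjusted p = 0.719). The red blood cell list had 1 measured member and the liver and gut list 2. The epithelial miR-200 family, striated muscle, Hox cluster, miR-183 cluster and miR-297 group lists had 0 measured members among the 281 miRNAs. Across the 15 tested lists fry called 0, and camera with an estimated correlation called 0. The mean difference had the same sign in 4 of 4 runs for 5 lists, which were the neuron-enriched, blood vessel, Dlk1-Meg3, miR-181 and rRNA or tRNA lists.

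The values fitted here were set beside the authors' deposited table. Across miRNAs, which are not independent replicates, the log2 difference fitted here and the log2 fold change in the authors' deposited table correlated at Pearson r = 0.985 and Spearman rho = 0.981, and at r = 0.996 with the run term. The authors' deposited table has mean levels that differ from those of the 20 columns by up to 0.459 on the log2 scale, so its counts are not from the same values and cannot be compared directly with those here. Its p-values follow from its t scores at 39.8 degrees of freedom. Whether other samples entered that comparison is not given in the sources used here. The authors' table lists 66 miRNAs at an unadjusted p under 0.05, 20 higher and 46 lower with CBD, and 0 at an adjusted p under 0.05, with a lowest adjusted p of 0.0566. All 22 miRNAs at an unadjusted p under 0.05 here were among those 66, and so were 40 of the 42 found with the run term. The sign was shared by 66 of 66. The 10 smallest p in the authors' deposited short list belonged to miR-126a-3p, miR-338-3p, miR-434-5p, miR-153-3p, miR-126a-5p, miR-409-5p, miR-666-5p, miR-300-3p, miR-151-5p and miR-30c-2-3p. Each of them was also among the 20 smallest p here.

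**Figure D4:**
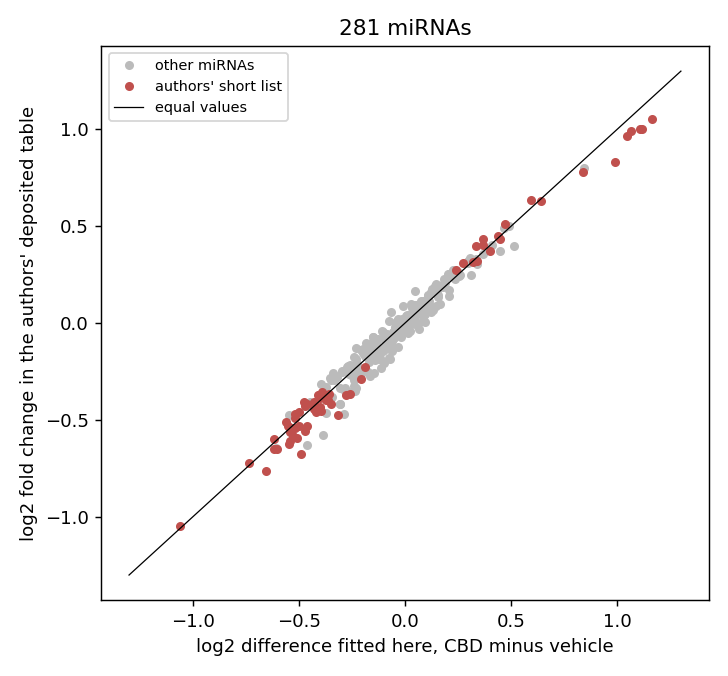
Log2 fold change of 281 miRNAs in the authors' deposited table (vertical) against the log2 difference fitted here, CBD minus vehicle (horizontal); red points are the 66 miRNAs of the authors' short list and the line marks equal values. The points follow the line (Pearson r = 0.985 across miRNAs).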

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

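The test on vehicle replicate 7 and that on the share of cell types were chosen after the values they bear on had been seen. In 74 sets of 10 values (32 miRNAs and 5 library measures in 2 groups), 7 held a value far from the other 9 of its group by the gap to its nearest neighbour, where chance gives about 3.7. The clearest was miR-219a-2-3p, an oligodendrocyte miRNA, at 9.53 on the log2 scale in vehicle replicate 7, against 7.21 ± 0.35 (SD) in the other 9 vehicle libraries. The neuronal miR-128-3p stood at 13.44 in vehicle replicate 5, against 14.69 ± 0.24 in the others. That library also had a scaling factor of 0.788, against 1.05 ± 0.0609, and the lowest read total, 242178. In vehicle replicate 4 miR-9-5p stood at 16.22, against 16.84 ± 0.16. In CBD replicate 8, a library with a scaling factor of 0.693, miR-30c-2-3p stood at 9.28, against 7.87 ± 0.28. The level of miR-370-3p was apart in both groups, at 7.47 in vehicle replicate 7, against 8.27 ± 0.20, and at 8.50 in CBD replicate 6, against 7.74 ± 0.17.

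The oligodendrocyte and blood vessel lists had negative means with CBD, and their calls depend on the setting. With treatment as the only term and the values as deposited, neither passed (camera adjusted p = 0.0503 each, adjusted p = 0.333 and 0.284 with an estimated correlation). The oligodendrocyte list did with the run term, at 0.0460 (adjusted p = 0.360 with an estimated correlation), and the blood vessel list did not, at 0.0669. The 95% intervals of their means were then -0.94 to -0.17 and -0.80 to -0.12. The oligodendrocyte mean was higher with CBD in run 4, by 0.11, and it was -0.17 with array weights, so its size is uncertain. In all, 3 explanations were weighed. Vehicle replicate 7 had the highest mean of all 20 libraries in several lists, among them choroid plexus and ependyma, 11.57, and the miR-17-92 cluster, 11.60. It had the highest mean of the oligodendrocyte list as well, 9.58. Without it the mean difference of the list was -0.38, 75.7% of that over all libraries, and the camera adjusted p was 0.220, the highest of the 20 fits that each left out 1 library, of which 8 called the list, so this library may account for a part of the difference and not for most of it. A smaller share of non-neuronal cells in the CBD samples should leave neuronal miRNAs higher. The mean difference of the neuron-enriched list with the run term was -0.21 (95% interval -0.43 to 0.01), and it was negative within 4 of 4 runs. No such rise was seen. How large a rise to expect is not known and the interval reaches just above 0, so this explanation is not excluded. An effect of CBD on these cells is also open and was not tested apart from the comparison itself.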

How the results depend on the processing

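The settings with run, voom weights, 5 added reads, quantile normalisation, median-of-ratios factors, GC slope, permutation within runs, array weights with run, the threshold of 0.1 for lists, and without the 3 libraries of low scaling factor were chosen after seeing the data. Other pseudocounts were not applicable to log2 values, and both other filters removed no miRNA, so they tested nothing. No paired analysis was possible because the labels give no pairing of CBD and vehicle mice. With a lowest read number of 2 and 77.2% of 2-fold changes recovered in simulated data without run effects, smaller changes can be missed.

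No miRNA passed adjustment in 23 other settings, among them both filter settings, which repeat the main fit. None passed with any single library left out (0 to 0), but 24 did with array weights. At a threshold of 0.1 the count without other changes was also 0, while the lowest adjusted p was under 0.1 with library reads (0.0884), permutation within runs (0.0937) and array weights with run (0.0576). At an unadjusted p under 0.05 there were 22 miRNAs, 57 with array weights with or without run, 42 with run as a term, as a random block or with GC slope, 39 with voom weights and run, and 41 with the exact permutation within runs. Leaving out 1 library gave 16 to 33.

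The number of called lists, 1, was 0 with camera at an estimated correlation, with run and GC slope, and with run without the 3 libraries. It was also 0 with fry, which asks another question, whether a list differs from no change. It was 2 with array weights, library reads, run as a term or random block, voom weights with run, and without the 3 libraries. It was 3 with median centring, mouse number, blocks of consecutive mouse numbers, quantile normalisation, median-of-ratios factors, and array weights with run, and 4 with voom weights, 5 added reads or a threshold of 0.1. Leaving out 1 library gave 0 to 4, with 0 without CBD replicate 4, vehicle replicate 6 or CBD replicate 9. Of 19 other settings that used camera at the preset correlation, 17 called the rRNA or tRNA list. Among these 17 were the variance models without a trend and with robust estimation, which do not enter the camera test and so repeat the main call. The oligodendrocyte and the blood vessel list were called in 10 settings each. Both of these were called with median centring, mouse number, blocks of mouse numbers, voom weights, 5 added reads, quantile normalisation and median-of-ratios factors. The oligodendrocyte list was also called with run as a term or random block and with voom weights and run, and the blood vessel list with library reads, without the 3 libraries, and with array weights and run. The cause was not tested.

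Among the values of named miRNAs under other settings, both filter settings included, 671 kept direction and side of the threshold, 14 passed it (all with array weights) and 19 turned sign. The log2 difference of the named miRNA mmu-mir-128-3p, -0.02, became 0.063 with median centring, 0.00477 with blocks of mouse numbers, 0.0027 with run, 0.033 with run and GC slope, 0.066 with quantile normalisation and 0.0036 with median-of-ratios factors. That of miR-21a-5p, -0.05, became 0.031 with median centring, 0.24 with array weights, 0.20 with array weights and run, 0.016 without the 3 libraries, 0.15 with run without them, 0.037 with run and GC slope and 0.0082 by Wilcoxon. That of miR-1983, -0.10, became 0.027 with array weights, 0.018 with quantile normalisation and 0.013 by Wilcoxon. Array weights turned miR-34a-5p to 0.011 and miR-219a-2-3p to 0.082, and quantile normalisation turned miR-9-5p to -0.031. Leaving out 1 library gave -0.14 to 0.049 for miR-128-3p, -0.21 to 0.14 for miR-21a-5p and -0.18 to 0.012 for miR-1983, and such fits kept direction and side in 629 values and turned the sign in 11.

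The mean of the miR-30 family, -0.01, became 0.072 with median centring, 0.010 with mouse number, 0.018 with run or with voom weights and run, 0.011 with run as a random block, 0.015 with quantile normalisation, 0.013 with median-of-ratios factors or without the 3 libraries, 0.060 with run and GC slope, 0.075 with run without the 3 libraries and 0.071 with array weights and run. The synapse list, -0.03, became 0.053 with median centring and 0.040 with quantile normalisation. The miR-34 family, -0.11, became 0.12 with run without the 3 libraries. Leaving out 1 library gave -0.043 to 0.37 for the choroid plexus list, -0.050 to 0.057 for the miR-30 family and -0.23 to 0.13 for the miR-34 family.

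Treatment held 6.83% of the squared distance between libraries, 11.6% (p = 0.0278) with run means removed, and 6.11 to 9.51% with 1 library left out (p = 0.0794 to 0.325). The difference in total reads was 0.084 (p = 0.789) on the log2 scale, and -68062 to 45309 reads with 1 library left out. That in listed miRNAs was then -6.54 to 22.5. The 135 miRNAs that differ between runs became 50 with GC slope and 85 with library reads as a term.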

Other observations

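The tests on GC content, depth and libraries of low scaling factor below, and the splits within runs or with array weights, were chosen after the main results had been seen, while the fits that each leave out 1 library were chosen before the data were examined. Beyond the named miRNAs, several others had an unadjusted p under 0.05 with the run term, chosen after their values were seen. Lower with CBD were miR-27a-3p at -0.50, miR-24-3p at -0.46, miR-23a-3p at -0.58, miR-151-3p at -0.40 and miR-148b-3p at -0.55. These 5 miRNAs had adjusted p between 0.225 and 0.252. The hairpins of miR-23a-3p and miR-27a-3p lie next to that of miR-24-2-5p on chromosome 8, while miR-24-3p has 2 hairpins, between which its reads cannot be told apart.

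With the run term 42 miRNAs had an unadjusted p under 0.05, where independent tests would give about 14.1 by chance. In 5 of 100 splits of the libraries within runs, the real one included, the count was at least 42, and the highest of the others gave 62, so chance cannot be excluded. Without the run term 16 of 100 splits gave at least 22, with 87 as the highest of the others, a number that points to a structure of the libraries apart from treatment. The count of 0 at an adjusted p under 0.05 leaves nothing to test, as any of the 100 splits gives at least 0, and the highest of the others gave 21. The 24 miRNAs called with array weights were matched by 7 of 100 splits, with 91 as the highest. The splits without the run term ignored run, while the real groups were nearly balanced over runs. A split that separates runs can give a large count, so such splits cannot decide whether the real counts exceed chance. Had a GC bias that differed between the groups produced the count with the run term, adding the GC slope of each library should have lowered it. The count stayed at 42 with that slope as a further term. A GC bias shared by both groups could not be seen in this way. The excess with the run term, 42, may be chance or small effects of treatment on many miRNAs, and these data leave both open.

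For the entries resembling rRNA or tRNA, 3 explanations were weighed. With the GC slope of each library added to the run term, the mean difference of the list kept 94.4% of its size, which argues against GC content as the whole cause of the difference, although the camera adjusted p went from 0.0460 to 0.0523 and the call was lost. Without the 3 libraries with a scaling factor under 0.8 it kept 115%, which argues against those libraries as its cause, although without them and with the run term the adjusted p was 0.0594. The list was called in 17 of the 20 fits that each left out 1 library, with adjusted p of 0.0531, 0.0615 and 0.0509 without CBD replicate 4, vehicle replicate 6 and CBD replicate 9, so single libraries may decide the call, while its mean difference stayed between 0.31 and 0.49. In 53 of 100 splits of the libraries that ignored run at least 1 list was called, with 6 as the highest of the others. With the run term, where 2 were called, at least 2 were called in 30 of 100 splits within runs, again with 6 as the highest, so chance cannot be excluded. A higher share of rRNA fragments in the CBD samples is open, since reads outside the 281 miRNAs are not analysed here.

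The run differences exceed chance. Only the real division gave as many as 135 miRNAs, 1 of 100 divisions into sets of the same sizes, and the highest of the others gave 31. With the GC slope of each library as a term 50 miRNAs still differed, and with log2 library reads 85. The mean GC slope was 0.18 (log2 per SD of GC) in run 2 and -0.15 in run 4, so a bias with GC content may account for much of the difference between runs and depth for less, although the slope was estimated from the same values. The mean of the choroid plexus and ependyma list also moved with run. It was 7.89 to 9.06 in the libraries of run 1, 7.87 to 10.06 in run 2, 10.36 to 11.57 in run 3 and 8.41 to 10.37 in run 4. No biological explanation was tested, as the sources used here do not say what differed between runs.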
